A study of Cellvibrio japonicus with 24 samples.

How the data were processed

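RNA was sequenced from wild-type Cellvibrio japonicus grown in MOPS defined medium on glucose, crab shell, GlcNAc or chitin and sampled in exponential or stationary phase. Per the labels, metabolism was stopped with a mixture of ethanol and phenol, total RNA was extracted, and libraries were made with standard Illumina protocols. Per the labels, HISAT2, HTSeq and DESeq2 were used; their versions, their settings and the genome build used for alignment are not given in the sources used here.

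The deposited HTSeq files hold raw counts per locus tag, 3876 features in each of 24 files, with no normalization. The deposited comparison tables, 12 in number, hold DESeq2 results per the file headers: log2 fold changes and their standard errors between groups, made by the authors from counts divided by size factors. The deposited tables also hold a Wald score per gene, as made by the authors with DESeq2. The p-value and adjusted p-value in each table were likewise computed by the authors with DESeq2. The baseMean column, per the file headers, is the mean over both groups of counts divided by size factors. CPM values were computed here from the deposited counts.

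The planned fit was of all 24 libraries in 8 groups. Because 4 pairs of files were identical, the fit was made instead with 20 distinct libraries in 7 groups, a change decided after seeing the data. The identical crab shell files were used as exponential and the file shared by GlcNAc and chitin in stationary phase was used as chitin. Of 16 planned comparisons 12 could be made from counts. Of the other 4, all with crab shell in stationary phase, 3 are described from the authors' tables alone and 1 is not used here; the interaction of crab shell with phase is not analysed here. No group sizes other than 3 occur, except 2 for GlcNAc in stationary phase. Group means were recovered from each authors' table from baseMean and the fold change, and compared with the libraries of the group after fitting a weight per library by least absolute deviation, over coding genes above a recovered mean of 20, features counted in some groups only left out; this was added after seeing the data. For CJA_0351 the ratio of counts, scaled for library size, has an exact interval for counting error only.

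Counts were fitted with edgeR 4.0.16 (R 4.3.3, limma 3.58.1) with filterByExpr by group, TMM scaling and robust quasi-likelihood tests, with 1 coefficient per group and 13 residual degrees of freedom. Of the features 3819 were tested, and 26 had no count in any library. The common biological coefficient of variation was 0.259. A gene counted as changed at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested, and the number with an absolute log2 fold change of at least 1 is given beside it. Standard errors were computed as the absolute log2 fold change over the square root of F. CPM used TMM-scaled library sizes. Correlations and principal components used log2 of CPM plus 1 over 3696 genes, without noncoding features and features counted in some groups only.

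Gene names came from the symbols in the deposited files, joined by coordinates, and from the reference table of locus tags for assembly ASM1922v1. Of the features 3559 matched a reference locus tag and 317 did not; 2658 were joined at both ends, 741 at the stop end, and 160 had a reference locus tag but no coordinates in the files. Names were found for 1358 features; of 627 genes with a symbol in both sources 535 had equal symbols. The authors' table of crab shell against GlcNAc in exponential phase carries coordinates and symbols that are not aligned with its locus tags, so these were joined anew. Gene lists were fixed by symbol rules before the files were seen. Of these lists 20 had at least 5 tested members and were tested with camera (limma) at a preset correlation of 0.01 between genes, adjusted over 240 list tests, and again with an estimated correlation. The GlcNAc catabolism and amino acid degradation lists have 3 members each and are given as counts. rRNA (9 members) and tRNA (46 members) genes were not tested as lists. Lists that could be formed only from product descriptions (TonB-dependent receptors, aminoacyl-tRNA synthetases, proteases and peptidases, phage genes, exopolysaccharide genes) are not analysed here.

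Genes were named by a rule fixed before the files were seen. For crab shell against glucose, GlcNAc and chitin, and for GlcNAc against glucose, all in exponential phase, the rule takes the 8 largest rises and 8 largest falls among genes that passed, had a mean of at least 20 CPM in the higher group and showed no overlap between libraries. Other comparisons take 3 each way. It also takes every chitin and GlcNAc gene and up to 4 genes of each other list. From these the text names examples. Features counted in some groups only were skipped in ranking, a choice made after seeing the data. For the authors' tables of crab shell in stationary phase the minimum was a normalized mean above 100 in the higher group in place of the CPM and overlap conditions.

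The procedure was tested on simulated data with the same library sizes, and with 1 mean and 1 spread per gene shared by all groups. A short list of other genes was raised 2-fold. Per comparison the procedure was given 200 changed genes, 50 each by 1.5, 2, 4 and 8-fold, with as many rises as falls. In the order given, it recovered 4%, 46%, 96% and 100% for crab shell against glucose, with 4 false calls (3% of calls); 4%, 62%, 90% and 100% for GlcNAc against glucose, with 6 (4.2%); and 6%, 52%, 98% and 100% for crab shell against GlcNAc, with 5 (3.6%). For crab shell against chitin it recovered 12%, 52%, 96% and 98%, with 3 false calls (2.2%); for chitin against GlcNAc in exponential phase 10%, 56%, 98% and 100%, with 7 (4.8%); and for chitin against glucose in exponential phase 12%, 58%, 96% and 100%, with 3 (2.1%). In stationary phase it recovered 18%, 36%, 92% and 100% for GlcNAc against glucose, with 7 false calls (5.3%); 4%, 50%, 96% and 100% for chitin against GlcNAc, with 10 (7.1%); and 14%, 52%, 96% and 100% for chitin against glucose, with 5 (3.6%). Between phases it recovered 4%, 40%, 90% and 100% for GlcNAc, with 1 false call (0.8%); 18%, 60%, 98% and 100% for glucose, with 6 (3.9%); and 12%, 54%, 92% and 98% for chitin, with 6 (4.3%). Changes of 1.5-fold were thus mostly missed at this depth and spread. The simulation does not cover the wider spread among the glucose stationary replicates. Nor does it cover comparisons in which most genes changed or in which scaling moved the median of all genes.

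Before the files were seen, these other settings were chosen: DESeq2's size factors, scaling by library totals only, no low-count filter, DESeq2 1.42.0, a fit of the compared groups alone, the replicate number as a block, rRNA and tRNA genes left out, a fold minimum, camera with an estimated correlation, fry (limma), and each library left out in turn. Chosen after seeing the data were all 24 files as labelled, the shared stationary file left out of both groups, features counted in some groups only left out, and glucose stationary replicate 1 as the only library of its group.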

Results

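Gene counts were deposited for wild-type Cellvibrio japonicus, a soil bacterium that breaks down polysaccharides, grown in MOPS defined medium on glucose, crab shell, chitin or N-acetylglucosamine (GlcNAc, the sugar unit of chitin). Cells were sampled in exponential or stationary phase, with 3 replicates for each of the 8 labelled groups. The chitin samples lie outside the carbon sources that the series' design statement lists. The 24 count files held 20 distinct libraries. Each of the 3 crab shell stationary files was identical, over all 3876 features, to the crab shell exponential file of the same number, and GlcNAc stationary replicate 1 was identical to chitin stationary replicate 3. The shared crab shell files were treated as exponential, because they lay closer to the crab shell exponential means in most of the authors' tables. With fitted library weights, the exponential mean differed from them by a median over genes of 0.0023 on the log2 scale in the comparisons with glucose and GlcNAc, 0.0173 in that with crab shell stationary and 0.0418 in that with chitin. The stationary mean differed by 0.463, 0.499 and 0.537 in the comparisons with crab shell exponential, glucose and chitin, but by 0.0513 in that with GlcNAc. These differences were computed after seeing the data. In that comparison with GlcNAc the GlcNAc stationary mean, too, lay closer to exponential counts. It correlated at r = 0.972 with GlcNAc exponential and 0.773 with GlcNAc stationary counts. The shared stationary file was treated as chitin: the chitin stationary libraries, this one included, correlated with each other at r = 0.969 to 0.993 across genes and with the other GlcNAc stationary libraries at r = 0.605 to 0.678. This left 2 libraries for GlcNAc in stationary phase and 3 in each of the other 6 groups. Total counts were 7449807 to 7579512 per library for glucose exponential and 6004177 to 7762087 for glucose stationary. They were 4216283 to 5761719 for crab shell exponential, 5147696 to 6099755 for GlcNAc exponential, and 4950114 and 4957520 for GlcNAc stationary. The chitin libraries held 4378359 to 4488075 counts in exponential phase and 2298696 to 2650791 in stationary phase.

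Libraries separated by growth phase and carbon source. Principal components used log2 CPM (counts scaled to a common library size) of 3696 genes, without noncoding features and features counted in some groups only. The first component took 59.3% of the variance and the second 21.3%. Across genes, which are not independent replicates, replicates of glucose exponential correlated at r = 0.997, replicates of GlcNAc exponential at 0.996, and these groups with each other at 0.967 to 0.969. Crab shell exponential libraries correlated more closely with GlcNAc stationary (0.824 to 0.856) than with GlcNAc exponential libraries (0.668 to 0.762). The chitin phases correlated with each other at 0.905 to 0.959. The glucose stationary replicates were the least alike, at 0.732 to 0.915. In glucose stationary replicates 2 and 3 the lower quartile of counts per kilobase was 1.38 and 1.30 times the 5th percentile, against 2.29 to 4.13 times in every other library, so their low genes lay close to an even floor. In the chitin libraries the 5th percentile was 0.155 to 0.185 of the mean, against 0.024 to 0.06 in the crab shell, GlcNAc and exponential glucose libraries. A smaller floor in the chitin libraries is not excluded, which bears on every comparison with chitin. The protein-coding gene CJA_1971, whose function the files do not give, took 2.68% to 10.7% of the counts in crab shell exponential and 5.91% to 10.7% in glucose stationary libraries, and at most 1.52% elsewhere. A set of 77 features, 47 of them noncoding, had counts in every library of GlcNAc exponential, GlcNAc stationary and chitin stationary and 0 in every other library. They took 11.01% to 25.4% of the counts of those libraries, and the transfer-messenger RNA gene ssrA alone took 6.84% to 15.9%. The sources used here do not give the cause. Fold changes of these features are not reported.

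**Figure D1:**
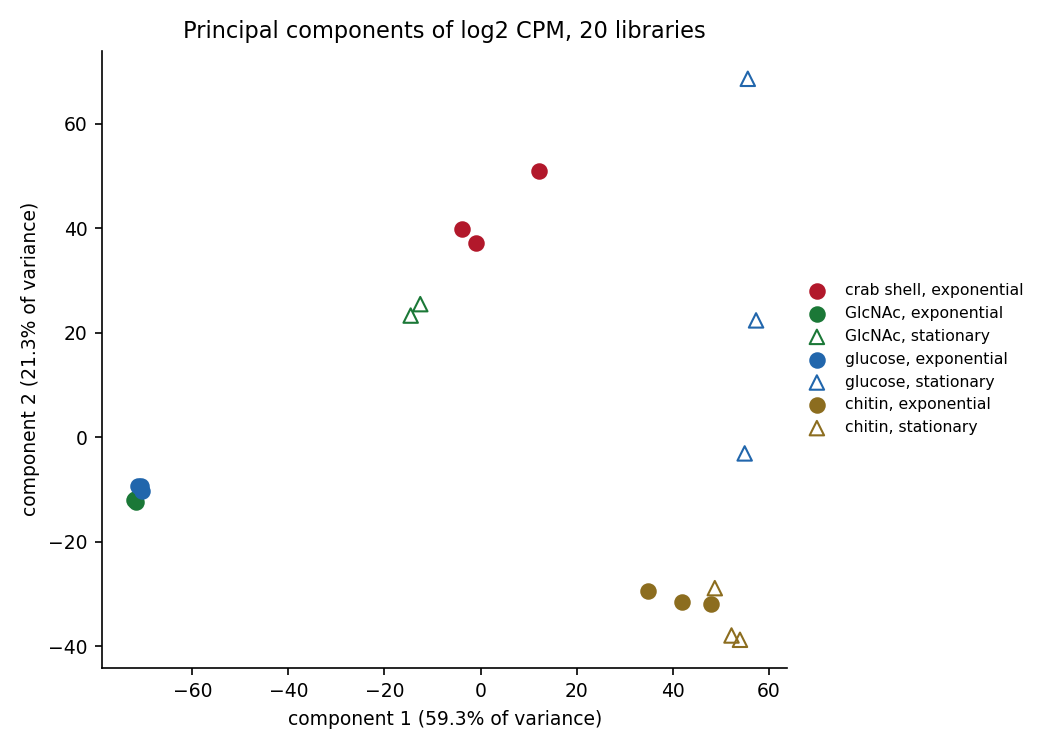
Principal components of log2 CPM of the 20 libraries, with component 1 (59.3% of the variance) on the horizontal and component 2 (21.3%) on the vertical axis; each point is a library, filled for exponential and open for stationary phase. The glucose and GlcNAc exponential libraries lie together, the glucose stationary libraries spread over component 2, and the chitin libraries of both phases lie near each other.

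Crab shell against glucose in exponential phase asks which genes respond to a chitin-rich natural substrate. It does not isolate the response to chitin. Between the glucose phases, without chitin, all genes of the chitin degradation list also rose in stationary phase, each by less than on crab shell. There chi18B rose by 2.94 ± 0.47 and cbp33A by 1.12 ± 0.25. CJA_0381, CJA_0382, coxB, coxG and clpA, named below, rose by more there than on crab shell. Some glucose stationary libraries lay near an even floor. All 9 genes of the chitin degradation list rose on crab shell. The lytic polysaccharide monooxygenase gene cbp33A (CJA_2191) rose by 6.78 ± 0.32 on the log2 scale (fold change ± standard error, as throughout), from 33.1 ± 6.39 CPM (SD, n = 3, as throughout unless stated) on glucose to 3649 ± 696 CPM on crab shell. The chitinase genes chi18D (CJA_2611), chi18C (CJA_2993), chi18B (CJA_0988), chi18A (CJA_1182) and chi19A (CJA_0996) rose by 6.59 ± 0.37, 5.50 ± 0.41, 3.23 ± 0.47, 3.19 ± 0.36 and 3.11 ± 0.36. The hexosaminidase genes hex20B (CJA_0287) and hex20A (CJA_0350) rose by 4.40 ± 0.41 and 1.16 ± 0.25, and a further lytic polysaccharide monooxygenase gene, cbp33/10B (CJA_3139), rose by 3.88 ± 0.33. The GlcNAc kinase gene nagK (CJA_1160), the deacetylase gene nag9A (CJA_1163) and the deaminase gene nagB (CJA_1164) rose by 4.14 ± 0.59, 2.97 ± 0.41 and 3.01 ± 0.38, so all 3 members of the GlcNAc catabolism list rose. On the 1 chromosome of assembly ASM1922v1, cbp33A lies at positions 2525166 to 2526359, chi18D at 3058857 to 3060623, nagK at 1364143 to 1365066 and nagB at 1368872 to 1369663. The chitin list had a median log2 fold change of 3.88 (camera adjusted p = 3.68e-08, and adjusted p = 0.262 with an estimated correlation).

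Among the largest rises were neighbouring genes that the files leave unnamed. CJA_3057, CJA_3056, CJA_3055 and CJA_3054 rose by 10.16 ± 0.71, 9.28 ± 0.64, 8.99 ± 0.70 and 8.26 ± 0.51, and mopR (CJA_3060) beside them by 7.91 ± 0.36. CJA_3054 went from 9.90 ± 0.27 to 3043 ± 289 CPM. CJA_3054 to mopR span positions 3627712 to 3633162. CJA_0381 and CJA_0382, also unnamed, rose by 8.39 ± 0.90 and 7.95 ± 0.91. Among the largest falls were CJA_2606 at -6.30 ± 0.33, its neighbour etfA (CJA_2605, an electron transfer flavoprotein gene) at -4.32 ± 0.28, the acyl carrier protein gene acpP (CJA_1677) at -3.84 ± 0.51 and the alanine racemase gene alr (CJA_0676) at -3.72 ± 0.22.

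Genes of translation, energy metabolism and biosynthesis fell on crab shell. Of 53 ribosomal protein genes 52 fell, 0 rose and 1 did not pass, with a median of -2.19 (camera adjusted p = 5.63e-12, and adjusted p = 0.622 with an estimated correlation). The gene rplL (CJA_0691) fell from 14344 ± 559 to 1189.7 ± 516 CPM, and rplU (CJA_0458) changed by -3.40 ± 0.37. All 14 ATP synthase and NADH dehydrogenase genes fell (median -1.89, camera adjusted p = 4.10e-05, and adjusted p = 0.619 with an estimated correlation), among them atpE (CJA_3814) at -3.02 ± 0.31. Of 67 amino acid biosynthesis genes 50 fell, 4 rose and 13 did not pass (median -1.26, camera adjusted p = 1.69e-07, and adjusted p = 0.383 with an estimated correlation). The aspartate kinase gene lysC (CJA_1360) and the branched-chain amino acid gene ilvC (CJA_0668) changed by -2.81 ± 0.27 and -2.60 ± 0.30. Of 14 glycolysis and Entner-Doudoroff genes 12 fell, 1 rose and 1 did not pass (median -1.37, camera adjusted p = 0.00162, and adjusted p = 0.455 with an estimated correlation), with the enolase gene eno (CJA_2225) at -2.51 ± 0.24 and CJA_2671 at -3.21 ± 0.26. Of 15 TCA and glyoxylate cycle genes 12 fell, 1 rose and 2 did not pass (median -1.38, camera adjusted p = 0.00397, and adjusted p = 0.692 with an estimated correlation), with the succinate dehydrogenase gene sdhD (CJA_1502) at -2.72 ± 0.23. Among 3 glycine cleavage genes on the amino acid degradation list, gcvT (CJA_0421) fell (-1.16 ± 0.22) and the other 2 did not pass.

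Among other polysaccharide-degrading genes, and among flagellum and chemotaxis genes, more rose than fell. Of 72 plant polysaccharide degradation genes 43 rose, 6 fell and 23 did not pass (median 0.81, camera adjusted p = 7.25e-05, and adjusted p = 0.581 with an estimated correlation). The cellulase genes cel6A (CJA_2473) and cel9A (CJA_2472) rose by 4.34 ± 0.40 and 3.23 ± 0.53. Of 18 genes on the starch and alpha-glucan list, which also holds glycogen genes, 11 rose, 2 fell and 5 did not pass (median 1.29, camera adjusted p = 0.0391, and adjusted p = 0.312 with an estimated correlation), with amy13J (CJA_1302) at 2.99 ± 0.43 and mal77Q (CJA_1882) at 2.98 ± 0.51. Of 46 flagellum and chemotaxis genes 22 rose, 1 fell and 23 did not pass (21 rose and 1 fell adjusted over the list alone; median 1.04, camera adjusted p = 0.00892, and adjusted p = 0.983 with an estimated correlation). The chemotaxis genes cheY-1 (CJA_2947) and cheA-1 (CJA_2945) rose by 3.46 ± 0.37 and 3.29 ± 0.34. The starch call did not pass when all 24 files were used as labelled (adjusted p = 0.0512), a setting chosen after seeing the data.

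The remaining lists did not pass in camera. Of 7 starvation and stationary phase genes 5 rose, 1 fell and 1 did not pass (median 1.78, camera adjusted p = 0.177). The ribosome modulation factor gene rmf (CJA_2157) rose from 318 ± 19.7 to 8082 ± 4560.4 CPM. Of 7 sigma factor genes 2 rose, 1 fell and 4 did not pass (median 0.06, camera adjusted p = 0.879), with the stationary phase sigma factor gene rpoS (CJA_2218) at 2.64 ± 0.56 and the housekeeping gene rpoD (CJA_0764) at -0.75 ± 0.21. The fall of rpoD did not pass when libraries were scaled by totals only (-0.57, adjusted p = 0.0917). Of 16 chaperone and ATP-dependent protease genes 4 rose, 2 fell and 10 did not pass (median 0.24, camera adjusted p = 0.681), with the small heat shock gene hspC2 (CJA_1092) at 5.53 ± 0.66 and clpA (CJA_2568) at 2.85 ± 0.66. Of 16 phosphate genes 8 rose, 1 fell and 7 did not pass (median 0.50, camera adjusted p = 0.282), with phoH (CJA_1389) at 5.29 ± 0.61. Of 10 iron genes 3 rose, 2 fell and 5 did not pass (median 0.25, camera adjusted p = 0.683), with exbB1 (CJA_2328) at 2.22 ± 0.42. Of 12 nitrogen genes 4 rose, 5 fell and 3 did not pass (median -0.22, camera adjusted p = 0.847), with nirD (CJA_0325) at 2.05 ± 0.29 and the glutamate dehydrogenase gene gdhA (CJA_2152) at -2.26 ± 0.21. Of 7 oxidative stress genes 3 rose, 3 fell and 1 did not pass (median 0.03 and mean 0.24, with camera's direction down, adjusted p = 0.879), with CJA_2891 at 4.31 ± 0.56 and the thioredoxin reductase gene trxB (CJA_2561) at -1.88 ± 0.21. Of 14 sulfur genes 6 rose, 4 fell and 4 did not pass (median 0.23 but mean -0.008, camera adjusted p = 0.914), with cysP (CJA_2349) at 1.86 ± 0.39 and cysNC (CJA_2121) at -2.52 ± 0.27. Of 11 terminal oxidase genes 5 rose, 5 fell and 1 did not pass (median -0.31 but mean 0.85, camera adjusted p = 0.820), and coxB (CJA_0865) and coxG (CJA_0867) rose by 5.17 ± 0.63 and 5.12 ± 0.59. Of 16 genes on the type II secretion list 2 rose, 7 fell and 7 did not pass (median -0.35, camera adjusted p = 0.829). The 2 rises were srpH (CJA_2237) at 2.84 ± 0.23 and epsG (CJA_0622) at 2.36 ± 0.26, neither with a gsp name. The list was formed by symbol, and whether these 2 genes act in type II secretion was not checked. Of 16 type IV pilus genes 4 rose, 3 fell and 9 did not pass (3 rose and 2 fell adjusted over the list alone; median -0.36 but mean 0.21, camera adjusted p = 0.951), with CJA_2401 at 4.08 ± 0.51. For every other list of this comparison the counts adjusted over the list alone were the same as those over all genes.

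Over all 3819 genes tested, 2566 differed between crab shell and glucose (1236 higher and 1330 lower on crab shell; edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05), and 1907 of these by at least 2-fold. The adjusted p of the named genes ran from 1.42e-10 for cbp33A to 0.00492 for rpoD, and each gene named as passing by rank lay higher in every library of one group than in any of the other. Scaling by library totals alone shifted the median of all genes by 0.178. The rise of hex20A did not pass when all 24 files were used as labelled (1.16, adjusted p = 0.0524).

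**Figure D2:**
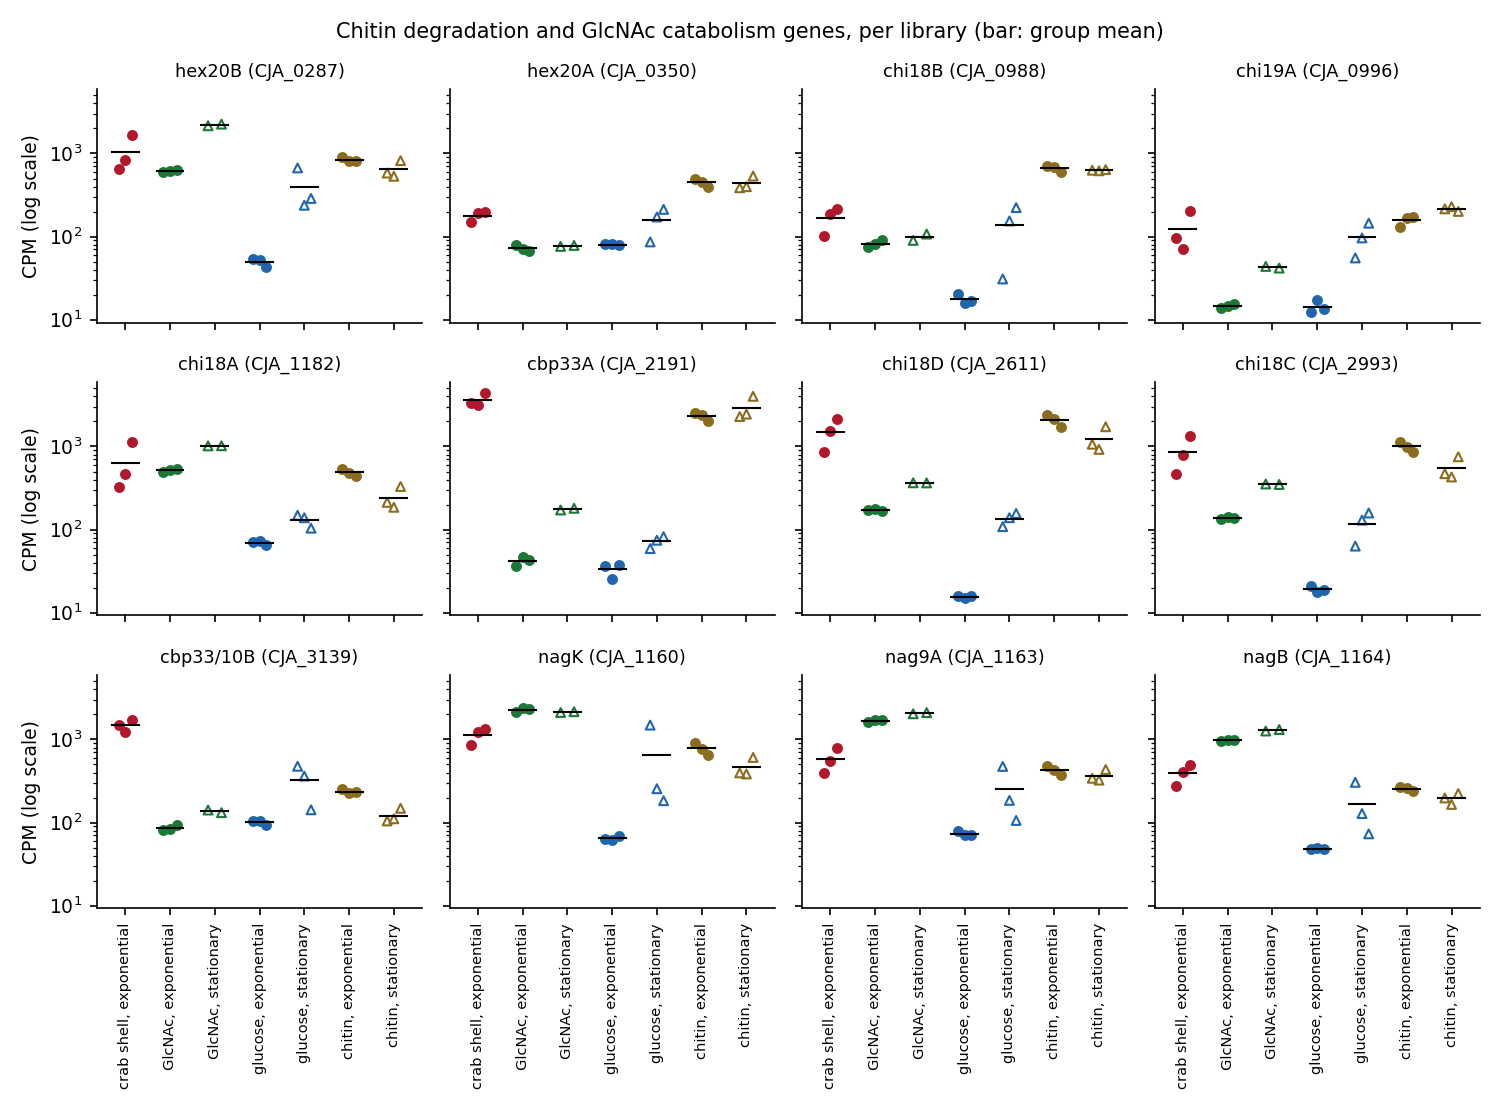
CPM on a log scale (vertical axis) of the 9 chitin degradation genes and 3 GlcNAc catabolism genes in each library of the 7 groups (horizontal axis); points are libraries, filled for exponential and open for stationary phase, and bars are group means. Expression of cbp33A is high on crab shell and chitin and low on GlcNAc and glucose, while nagK, nag9A and nagB are highest on GlcNAc.

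GlcNAc against glucose in exponential phase asks how far the sugar unit of chitin alone changes expression. Genes of GlcNAc use rose in a cluster at positions 1358777 to 1369663, in the counts and in the authors' table. CJA_1157 rose by 7.30 ± 0.79, from 71.2 ± 3.36 to 11195 ± 393 CPM. The genes gluP (CJA_1161), nagK, nag9A and nagB rose by 5.16 ± 0.49, 5.15 ± 0.62, 4.50 ± 0.43 and 4.33 ± 0.40, so 3 of 3 members of the GlcNAc catabolism list rose. Of the 9 chitin degradation genes 5 rose, 0 fell and 4 did not pass, the same adjusted over the list alone (median 2.21, camera adjusted p = 0.00118, and adjusted p = 0.474 with an estimated correlation). These were hex20B at 3.63 ± 0.40, chi18D at 3.46 ± 0.32, chi18A at 2.88 ± 0.35, chi18C at 2.84 ± 0.37 and chi18B at 2.21 ± 0.46. Neither lytic polysaccharide monooxygenase gene passed: cbp33A had a log2 fold change of 0.34 ± 0.26 (adjusted p = 0.597) and cbp33/10B of -0.22 ± 0.30 (adjusted p = 0.847). CJA_0058 and CJA_2724 fell by 2.72 and 2.26 on the log2 scale, with standard errors of 0.37 and 0.29, and the glucokinase gene glk (CJA_1496) changed by -1.08 ± 0.20.

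Few members of the other lists passed between GlcNAc and glucose in the fit of all 7 groups. Of 53 ribosomal protein genes 2 fell and 51 did not pass (1 fell adjusted over the list alone). These were rpmG (CJA_3514) at -2.32 ± 0.28 and rpmH (CJA_3826) at -0.91 ± 0.27, and neither passed in the authors' table (-0.02, adjusted p = 0.790, and -0.11, adjusted p = 0.104). The call of rpmH was lost without any 1 of the 6 libraries (adjusted p = 0.0824 to 0.148), with DESeq2's size factors (0.0624), with the replicate number as a block (0.0631) and with all 24 files as labelled (0.148). The plant polysaccharide list had 3 falls among 72 genes, including gly43G (CJA_3070) at -1.16 ± 0.15, a call not made when all 24 files were used as labelled (adjusted p = 0.197). None of the 46 flagellum and chemotaxis genes passed, at a median of -0.50 (camera adjusted p = 0.0427, and adjusted p = 0.983 with an estimated correlation). This list did not pass without GlcNAc_Exp replicate 3 (adjusted p = 0.0569). Some members that did not pass here passed by the authors' DESeq2 test: fliD (CJA_1916) at -0.78 (adjusted p = 5.47e-46), cheA (CJA_2138) at -0.35 (6.42e-11), groL (CJA_2646) at 0.83 (1.11e-47) and dnaK (CJA_3347) at 0.76 (1.64e-52). Others, such as sucA (CJA_1505) at 0.02 (0.795) and fur (CJA_3352) at -0.03 (0.704), passed in neither. In total 367 genes differed (202 higher and 165 lower on GlcNAc; edgeR), 267 by at least 2-fold, and 76 of the 367 were among the features counted in some groups only. Fitting these 6 libraries alone gave 1911 genes, and cbp33A then passed (0.41, adjusted p = 0.0167). The authors' table, whose fold changes correlated with these at r = 0.829 across genes, gave 1455 (716 higher and 739 lower). The authors' log2 fold changes were close for some genes (7.30 for CJA_1157, 5.11 for gluP, 5.73 for nagK, 4.52 for nag9A, 4.42 for nagB and -2.38 for CJA_0058), but not for many of the largest changes. The disagreement lay on the GlcNAc side: the GlcNAc mean recovered from this table differed from the GlcNAc exponential libraries by a median of 0.0719 on the log2 scale, and by more than 2-fold for 0.85% of genes, while the glucose mean differed by 0.002. In the authors' tables of crab shell and chitin against GlcNAc the GlcNAc mean differed alike, by 0.0721 and 0.072. CJA_0351 had 843 counts on GlcNAc and 2 on glucose, a ratio of 687 after scaling for library size, against a log2 fold change of 4.89 in their table. The exact 95% interval of the ratio, 189.5 to 5680.03, covers counting error only and not the variation between replicates. Their value and that from the counts were 0.55 and 7.30 ± 0.34 for CJA_2644, 0.63 and 5.78 ± 0.39 for CJA_2643, 0.02 and 5.18 ± 0.49 for CJA_1699, and -0.006 and 4.85 ± 0.45 for CJA_1509. Among the falls they were -1.35 and -3.87 ± 0.50 for CJA_3293, -0.04 and -3.07 ± 0.33 for CJA_2464, -0.43 and -2.88 ± 0.35 for CJA_3475, and -0.02 and -2.32 ± 0.28 for rpmG. Library totals alone shifted the median by -0.270; the share of changed genes that were higher on GlcNAc was 55.0%, against 39.1% by totals and 65.5% with DESeq2's size factors. The rise of chi18B did not pass by totals (1.94, adjusted p = 0.0596).

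Crab shell against GlcNAc in exponential phase sets the natural shell against the sugar unit of chitin. It does not isolate the polymer, since the crab shell libraries lay closer to GlcNAc stationary than to GlcNAc exponential libraries. In addition, only the GlcNAc libraries held the features counted in some groups only. Between the GlcNAc phases, without any polymer, cbp33A, phoH, rmf and rpoS also rose. The lytic polysaccharide monooxygenase genes were far higher on crab shell: cbp33A by 6.44 ± 0.32 (3649 ± 696 against 42.1 ± 5.06 CPM) and cbp33/10B by 4.10 ± 0.33. Also higher were chi18D, chi19A, chi18C and hex20A, by 3.14 ± 0.31, 3.08 ± 0.37, 2.66 ± 0.36 and 1.31 ± 0.25. For chi18B the difference was 1.02 ± 0.43 (adjusted p = 0.0444), for hex20B 0.78 ± 0.36 (adjusted p = 0.0611) and for chi18A 0.31 ± 0.33 (adjusted p = 0.415), so that 7 of 9 chitin degradation genes were higher (8 adjusted over the list alone; median 2.66, camera adjusted p = 9.62e-04, and adjusted p = 0.474 with an estimated correlation). The GlcNAc genes nag9A and nagB were lower on crab shell, at -1.54 ± 0.38 and -1.32 ± 0.35, and nagK, at -1.01 ± 0.52, did not pass (adjusted p = 0.0953). The call of chi18B was lost without any 1 of CRB_Exp replicate 2 (adjusted p = 0.102), CRB_Exp replicate 3 (0.148), GlcNAc_Exp replicate 1 (0.111), GlcNAc_Exp replicate 2 (0.0953) or GlcNAc_Exp replicate 3 (0.0684). It was also lost with DESeq2's size factors (0.0645), all 24 files as labelled (0.146), the shared stationary file left out (0.0530) or the features counted in some groups only left out (0.0505). Without CRB_Exp replicate 1 or 2, hex20B passed (1.03, adjusted p = 0.0212, and 0.92, adjusted p = 0.0480), as it did by totals (1.25, adjusted p = 0.00225), in a fit of these 6 libraries (0.78, adjusted p = 0.0433) and with the features counted in some groups only left out (0.80, adjusted p = 0.0435). The gene nagK passed in a fit of these 6 libraries (-0.99, adjusted p = 0.00296). Without CRB_Exp replicate 3 chi18A turned to -0.37 (adjusted p = 0.187).

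Most flagellum, chemotaxis and polysaccharide genes were higher, and ribosomal protein and ATP synthase genes lower, on crab shell than on GlcNAc. Of 46 flagellum and chemotaxis genes 40 were higher, 0 lower and 6 did not pass (median 1.60, camera adjusted p = 3.37e-04, and adjusted p = 0.964 with an estimated correlation), with the anti-sigma factor gene flgM (CJA_1936) at 3.53 ± 0.57, cheA-1 at 3.52 ± 0.34 and the filament cap gene fliD (CJA_1916) at 3.08 ± 0.60. Of 72 plant polysaccharide genes 46 were higher, 5 lower and 21 did not pass (median 1.00, camera adjusted p = 1.93e-05, and adjusted p = 0.512 with an estimated correlation), with cel6A at 5.09 ± 0.42 and cel5B (CJA_2983) at 3.68 ± 0.27. Of 18 starch and alpha-glucan genes 12 were higher and 2 lower (median 1.23, camera adjusted p = 0.0337, and adjusted p = 0.312 with an estimated correlation), with amy13J at 3.33 ± 0.44. Of 53 ribosomal protein genes 51 were lower, 0 higher and 2 did not pass (median -2.04, camera adjusted p = 1.18e-07, and adjusted p = 0.762 with an estimated correlation); rplU and rplL were at -3.43 ± 0.37 and -3.12 ± 0.44. All 14 ATP synthase and NADH dehydrogenase genes were lower (camera adjusted p = 6.33e-04, and adjusted p = 0.684 with an estimated correlation), with atpE at -3.30 ± 0.32. Single genes higher on crab shell were phoH (5.68 ± 0.62), coxB (5.29 ± 0.64), rmf (5.15 ± 0.67), hspC2 (4.65 ± 0.63) and rpoS (3.34 ± 0.58). Among the largest differences were CJA_3057 at 9.91 ± 0.72, CJA_0381 at 9.20 ± 0.95, mopR at 8.39 ± 0.37 and CJA_1971 at 8.10 ± 0.75. CJA_2606 was at -4.59 ± 0.31. CJA_2644 was at -7.24 ± 0.35 from the counts but -0.83 in the authors' table. In total 2698 genes differed (1334 higher and 1364 lower on crab shell; edgeR), 2035 by at least 2-fold. Scaling by totals shifted the median by 0.449 and DESeq2's size factors by -0.114; the share higher was 49.4%, or 66.3% by totals.

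Crab shell against chitin in exponential phase compares the natural shell with the polymer. Of the 9 chitin degradation genes 2 were higher, 2 lower and 5 did not pass, the same adjusted over the list alone (median -0.20, camera adjusted p = 0.879). cbp33/10B was higher on crab shell by 2.65 ± 0.31, while hex20A and chi18B were lower, at -1.32 ± 0.24 and -1.99 ± 0.44. For cbp33A the difference of 0.66 ± 0.25 (adjusted p = 0.0251; 3649 ± 696 against 2304 ± 269 CPM) rested on the settings: it was 0.42 with DESeq2's size factors (adjusted p = 0.125) and with DESeq2 (adjusted p = 0.0748), -0.43 by library totals (adjusted p = 0.351) and 0.30 in a fit of these 6 libraries (adjusted p = 0.329). It also did not pass without CRB_Exp replicate 3 (0.50, adjusted p = 0.109) or Chitin_Exp replicate 3 (0.57, adjusted p = 0.0828). All 53 ribosomal protein genes were higher on crab shell (median 1.59, camera adjusted p = 2.70e-06, and adjusted p = 0.833 with an estimated correlation), with rpsO (CJA_0439) at 3.50 ± 0.56 and rpsT (CJA_0852) at 2.45 ± 0.37. All 16 chaperone and protease genes were higher as well (median 2.13, camera adjusted p = 5.77e-04, and adjusted p = 0.684 with an estimated correlation), with hspC2 at 3.64 ± 0.60, dnaK (CJA_3347) at 3.45 ± 0.62 and dnaJ (CJA_3346) at 3.23 ± 0.31. Of 16 type II secretion genes 12 were higher and 2 lower (median 1.41, camera adjusted p = 0.0251, and adjusted p = 0.684 with an estimated correlation), with gspC (CJA_3333) at 2.26 ± 0.25. The list did not pass without CRB_Exp replicate 3 (adjusted p = 0.0514). All 7 starvation genes were higher (camera adjusted p = 0.101), with relA (CJA_2575) at 2.84 ± 0.42 and rmf at 2.21 ± 0.58, and so were the 3 glycine cleavage genes, with gcvH (CJA_0420) at 2.63 ± 0.38.

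Plant and starch polysaccharide genes were higher on chitin. Of 18 starch and alpha-glucan genes 10 were lower on crab shell, 4 higher and 4 did not pass (median -1.17, camera adjusted p = 1.66e-04, and adjusted p = 0.0474 with an estimated correlation), with amy13A (CJA_2618) at -4.91 ± 0.47. Of 72 plant polysaccharide genes 40 were lower, 15 higher and 17 did not pass (median -0.74, camera adjusted p = 4.46e-04, and adjusted p = 0.622 with an estimated correlation), with the arabinofuranosidase genes abf43L (CJA_0806) and abf43M (CJA_0819) at -3.59 ± 0.37 and -3.33 ± 0.39. Also lower were CJA_2620, wapA (CJA_2619) and pvdP (CJA_1865), at -6.25 ± 0.62, -4.89 ± 0.30 and -5.28 ± 0.54, and CJA_1971, CJA_1093, tadA (CJA_1345) and CJA_0381 were higher, at 6.91 ± 0.71, 5.72 ± 0.78, 4.70 ± 0.64 and 4.48 ± 0.74. Of 67 amino acid biosynthesis genes 46 were higher on crab shell and 2 lower (median 0.93, camera adjusted p = 4.46e-04, and adjusted p = 0.583 with an estimated correlation), with dapA (CJA_2830) at 3.09 ± 0.44. Among the ATP synthase and NADH dehydrogenase genes 10 of 14 were higher (median 0.89, camera adjusted p = 0.0470, and adjusted p = 0.964 with an estimated correlation), with atpH (CJA_3812) at 2.26 ± 0.35, and among the glycolysis genes 11 of 14 (median 1.10, camera adjusted p = 0.0202, and adjusted p = 0.622 with an estimated correlation). Each of these counts was the same adjusted over the list alone. By library totals the medians of the ribosomal protein, chaperone and type II secretion lists came down to 0.52, 1.02 and 0.32 and those of the starch and plant lists moved to -2.28 and -1.86, all still passing. Those of the amino acid, ATP synthase and glycolysis lists were -0.15, -0.19 and -0.005, and the ATP synthase and glycolysis calls were lost (adjusted p = 0.0687 and 0.143), as they were in a fit of these 6 libraries (0.0887 and 0.0895) and with all 24 files as labelled (0.0958 and 0.0767). The ATP synthase call was also lost without CRB_Exp replicate 2 (adjusted p = 0.110), CRB_Exp replicate 3 (0.0789) or Chitin_Exp replicate 3 (0.0938). In total 2655 genes differed (1553 higher and 1102 lower on crab shell; edgeR), 1928 by at least 2-fold. Scaling by totals shifted the median by -1.10 and DESeq2's size factors by -0.239; the share higher was 58.5%, 19.4% by totals, and 46.4% when the features counted in some groups only were left out of the fit, a setting chosen after seeing the data.

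Chitin against the single sugars in exponential phase was compared for each sugar in turn. Counts per kilobase had a higher 5th percentile, relative to the mean, on chitin than on these sugars. A smaller floor under the low genes on chitin is therefore not excluded. Against glucose all 9 chitin degradation genes rose on chitin (median 4.08, camera adjusted p = 6.26e-06, and adjusted p = 0.314 with an estimated correlation), with chi18D at 7.05 ± 0.38, cbp33A at 6.12 ± 0.31 and chi18C at 5.70 ± 0.42, and nagK rose by 3.60 ± 0.58. Against GlcNAc 7 of the 9 were higher and 2 did not pass (median 2.86, camera adjusted p = 0.00389, and adjusted p = 0.495 with an estimated correlation), with cbp33A at 5.77 ± 0.31, chi18D at 3.60 ± 0.32 and chi18B at 3.01 ± 0.46, while nagB was lower (-1.93 ± 0.36, or -0.38 with adjusted p = 0.0962 by totals). All 53 ribosomal protein genes were lower than on glucose (median -3.67, camera adjusted p = 2.03e-16, and adjusted p = 0.495 with an estimated correlation) and than on GlcNAc (median -3.46, camera adjusted p = 5.63e-12, and adjusted p = 0.619 with an estimated correlation). rplL fell by 5.54 on the log2 scale against glucose, acpP changed by -5.77 ± 0.56 against glucose, and rplU, atpE and the chaperonin gene groL (CJA_2646) by -5.40 ± 0.41, -4.01 ± 0.33 and -4.02 ± 0.37 against GlcNAc. Starch and alpha-glucan genes rose against both: 17 of 18 against glucose and 17 of 18 against GlcNAc (medians 1.87 and 2.12; camera adjusted p = 3.25e-06 and 6.85e-06, and adjusted p = 0.0171 for both with an estimated correlation), with amy13A at 5.36 ± 0.48 and 5.22 ± 0.48 and amy13C (CJA_1402) at 4.48 ± 0.17 against GlcNAc. Plant polysaccharide genes rose in 51 of 72 cases against glucose (52 adjusted over the list alone; median 1.66, camera adjusted p = 1.04e-08, and adjusted p = 0.392 with an estimated correlation) and 55 of 72 against GlcNAc (median 1.89, camera adjusted p = 5.14e-09, and adjusted p = 0.383 with an estimated correlation). Examples are abf43M, at 4.42 ± 0.41 and 4.69 ± 0.42, and cel9A, at 4.37 ± 0.56 against GlcNAc. Among the terminal oxidase genes coxG was higher than on GlcNAc by 4.96 ± 0.61. In total 2899 genes differed from glucose (1306 higher and 1593 lower) and 2973 from GlcNAc (1363 higher and 1610 lower; edgeR), 2337 and 2435 of them by at least 2-fold. By totals the medians of the ribosomal protein list were -2.42 and -1.93. The medians of all genes shifted by 1.28 and 1.55 by totals, and by DESeq2's size factors by 0.221 and 0.125. The shares higher on chitin were 45.1% and 45.8%, 78.1% and 81.4% by totals, and 55.8% and 55.9% without the features counted in some groups only.

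In stationary phase, ribosomal protein and energy metabolism genes were higher on GlcNAc than on glucose. All 53 ribosomal protein genes were higher on GlcNAc (median 3.82, camera adjusted p = 7.12e-19, and adjusted p = 0.495 with an estimated correlation), with rpmC (CJA_0707) at 4.75 ± 0.44 (n = 2 and 3). All 14 ATP synthase and NADH dehydrogenase genes were higher (median 3.45, camera adjusted p = 2.03e-08, and adjusted p = 0.474 with an estimated correlation), with atpE at 4.35 ± 0.35. So were 14 of 15 TCA and glyoxylate genes, with 1 not passing (median 3.34, camera adjusted p = 5.61e-09, and adjusted p = 0.400 with an estimated correlation), among them the succinyl-CoA synthetase gene sucC (CJA_1508) at 5.15 ± 0.39. ilvC was higher by 6.21 ± 0.36, at 5229.7 ± 277 against 70.3 ± 20.1 CPM, and the oxidase gene ccoN (CJA_2634) by 4.50 ± 0.26. The GlcNAc genes nag9A and nagB were higher by 3.02 ± 0.43 and 2.94 ± 0.39, chi18A by 2.97 ± 0.37 and hex20B by 2.47 ± 0.40. Of the 9 chitin degradation genes 5 were higher, 3 lower and 1 did not pass (median 1.29, camera adjusted p = 0.791). The lower ones were hex20A at -1.03 ± 0.28, chi19A at -1.22 ± 0.38 and cbp33/10B at -1.26 ± 0.34, and chi18B was at -0.47 ± 0.49 (adjusted p = 0.398). In a fit of the 5 libraries these 3 did not pass (adjusted p = 0.122, 0.105 and 0.0995), nor did chi18C (0.0712), and by totals cbp33A, chi18D and chi18C did not (0.365, 0.275 and 0.334). With Glc_Sta replicate 1 alone, its spread taken from the other groups, hex20A and chi19A did not pass (0.326 and 0.347) and chi18B was higher (1.61, adjusted p = 1.74e-04), while without that replicate chi18B was lower (-0.94, adjusted p = 0.00358). The call of chi19A was also lost without either GlcNAc_Sta library (adjusted p = 0.0533 and 0.0660) and with all 24 files as labelled (-0.06, adjusted p = 0.934), where hex20A turned to 0.54 (adjusted p = 0.379). Of 72 plant polysaccharide genes 61 were lower (median -1.45, camera adjusted p = 1.59e-11, and adjusted p = 0.325 with an estimated correlation), with cel5D (CJA_3010) at -2.98 ± 0.17. Also lower were the starch gene pul13B (CJA_3161) at -4.20 ± 0.50, coxB at -4.33 ± 0.72 and CJA_0382 at -7.73 ± 1.08. CJA_0065 was higher by 7.62 ± 0.29. In total 2579 genes differed (1275 higher and 1304 lower on GlcNAc; edgeR), 1953 by at least 2-fold. The authors' table gave 679, but its GlcNAc group was unlike the one fitted here: the GlcNAc mean recovered from it differed from the 2 GlcNAc libraries by a median of 0.229 on the log2 scale, and by more than 2-fold for 12.6% of genes, and the glucose mean by 0.0175. The glucose stationary replicates lay apart, and replicates 2 and 3 lay near an even floor. Fitting the 5 libraries alone gave 1009 genes and lost hex20B (adjusted p = 0.0596) and coxB (adjusted p = 0.0570). Totals shifted the median by -0.765 and moved the share higher from 49.4% to 25.1%. With all 24 files as labelled cel5D did not pass (adjusted p = 0.0530).

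Chitin in stationary phase was set against GlcNAc and glucose in the same phase. cbp33A was higher on chitin by 4.05 ± 0.33 against GlcNAc (2919 ± 951 CPM, n = 3, against 176 ± 5.94 CPM, n = 2) and by 5.34 ± 0.30 against glucose, and chi18D by 1.76 ± 0.35 and 3.20 ± 0.32. Against GlcNAc 5 chitin degradation genes were higher, 2 lower and 2 did not pass (median 1.76, camera adjusted p = 0.129), the lower ones being hex20B at -1.78 ± 0.39 and chi18A at -2.07 ± 0.36; nagB was at -2.72 ± 0.39. Against glucose 7 were higher, 1 lower and 1 did not pass (median 1.48, camera adjusted p = 0.0151, and adjusted p = 0.619 with an estimated correlation), the lower one being cbp33/10B at -1.43 ± 0.30. Ribosomal protein genes were lower than on GlcNAc in 51 of 53 cases (median -1.95, camera adjusted p = 1.41e-07, and adjusted p = 0.763 with an estimated correlation) and higher than on glucose in 44 of 53, with 1 lower (45 and 1 adjusted over the list alone; median 1.58, camera adjusted p = 1.43e-06, and adjusted p = 0.833 with an estimated correlation), with rpsC (CJA_0705) at 2.73 ± 0.35 against glucose. Plant polysaccharide genes were higher than on GlcNAc in 54 of 72 cases (median 1.87, camera adjusted p = 9.74e-13, and adjusted p = 0.307 with an estimated correlation), with abf43L at 4.18 ± 0.45 and cel9A at 3.86 ± 0.64. Motility genes were lower than on glucose: 28 of 46 flagellum and chemotaxis genes (4 higher; median -1.29, camera adjusted p = 0.00929, and adjusted p = 0.983 with an estimated correlation), with cheY (CJA_2140) at -3.81 ± 0.63, and 13 of 16 type IV pilus genes (2 higher; median -2.05, camera adjusted p = 0.0462, and adjusted p = 0.964 with an estimated correlation), with pilG (CJA_0080) at -3.26 ± 0.58. Without Glc_Sta replicate 1 neither motility list passed, and their medians moved to -0.46 (adjusted p = 0.134) and -0.99 (adjusted p = 0.184); the pilus list also did not pass without Chitin_Sta replicate 1 (0.0609) or Chitin_Sta replicate 2 (0.0533). Against glucose CJA_0381 was at -5.75 ± 0.79 and clpA at -3.88 ± 0.69. Against GlcNAc CJA_0065, CJA_3113 and ilvC were at -9.48 ± 0.32, -8.03 ± 0.28 and -4.68 ± 0.34, and the methionine synthase gene metE (CJA_2448) at 3.77 ± 0.59.

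In total 2676 genes differed between chitin and GlcNAc in stationary phase (1162 higher and 1514 lower on chitin; edgeR), 2151 by at least 2-fold, and 2656 between chitin and glucose (1320 and 1336), 1860 by at least 2-fold. The glucose stationary replicates lay apart, with replicates 2 and 3 near an even floor; with replicate 1 alone, its spread taken from the other groups, the chitin list did not pass although its median was higher (2.46, adjusted p = 0.0784). With all 24 files as labelled its median stayed at 1.48 and it did not pass either (adjusted p = 0.0804). Fitting the 6 chitin and glucose libraries alone gave 1576 genes. With all 24 files as labelled, so that 1 file stood in both groups, 1573 genes differed between chitin and GlcNAc, and cbp33A (1.00, adjusted p = 0.249), chi18D (0.60, adjusted p = 0.306), abf43L (1.31, adjusted p = 0.136) and metE (1.02, adjusted p = 0.272) did not pass. For chitin against GlcNAc totals shifted the median by 0.991 and DESeq2's size factors by 0.171, and the share higher was 43.4%, or 76.1% by totals. With that scaling the median of the ribosomal protein list was -0.96, and hex20B did not pass (-0.80, adjusted p = 0.0509). For chitin against glucose totals shifted the median by 0.226.

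Stationary against exponential phase was compared within each substrate. On GlcNAc 52 of 53 ribosomal protein genes fell in stationary phase and 1 did not pass (median -2.72, camera adjusted p = 2.32e-20, and adjusted p = 0.474 with an estimated correlation), with rplJ (CJA_0690) at -3.90 ± 0.52 (n = 2 and 3). On GlcNAc 35 of 46 flagellum and chemotaxis genes rose and 11 did not pass (37 rose adjusted over the list alone; median 1.53, camera adjusted p = 6.22e-07, and adjusted p = 0.765 with an estimated correlation), with cheY-1 at 4.64 ± 0.41. Also on GlcNAc, 9 of 18 starch and alpha-glucan genes rose and 2 fell (median 0.72, camera adjusted p = 0.00639, and adjusted p = 0.193 with an estimated correlation), with the glycogen phosphorylase gene gt35A (CJA_1605) at 4.30 ± 0.30 and mal77Q at 4.03 ± 0.56. phoH, rmf and rpoS rose by 6.05 ± 0.65, 3.97 ± 0.66 and 2.31 ± 0.59, cbp33A by 2.07 ± 0.28 and hex20B by 1.85 ± 0.39. CJA_3113 and CJA_0065 rose by 9.12 ± 0.30 and 8.26 ± 0.30, and metE and groL changed by -6.37 ± 0.67 and -3.02 ± 0.41. In total 2064 genes differed (963 higher and 1101 lower in stationary phase; edgeR), 1427 by at least 2-fold. Totals shifted the median by 0.415, and the share higher was 46.7%, or 72.8% by totals.

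On glucose all 53 ribosomal protein genes fell in stationary phase (median -6.74, camera adjusted p = 5.94e-21, and adjusted p = 0.493 with an estimated correlation), with rplL at -8.23 ± 0.56 and rplJ at -8.06 ± 0.53. All 14 ATP synthase and NADH dehydrogenase genes fell (median -5.07, camera adjusted p = 8.18e-08, and adjusted p = 0.495 with an estimated correlation), with atpE at -6.29 ± 0.37, and ilvC and the glycolysis gene CJA_2671 changed by -5.58 ± 0.34 and -6.02 ± 0.30. All 9 chitin degradation genes rose without chitin in the medium (median 2.61, camera adjusted p = 0.0151, and adjusted p = 0.583 with an estimated correlation), with chi18D at 3.11 ± 0.32 and chi18B at 2.94 ± 0.47. Of 72 plant polysaccharide genes 58 rose, 1 fell and 13 did not pass (median 1.67, camera adjusted p = 9.46e-08, and adjusted p = 0.455 with an estimated correlation), with pel1B (CJA_0533) at 3.55 ± 0.39. Of 18 starch and alpha-glucan genes 15 rose (median 2.23, camera adjusted p = 3.36e-04, and adjusted p = 0.0499 with an estimated correlation), with amy13J at 3.93 ± 0.45. Of 46 flagellum and chemotaxis genes 40 rose and 6 did not pass (median 1.57, camera adjusted p = 0.00222, and adjusted p = 0.983 with an estimated correlation), with cheY-1 at 4.07 ± 0.38. CJA_0381, CJA_0382, coxG, coxB and clpA rose by 9.02 ± 0.92, 8.58 ± 0.93, 7.10 ± 0.64, 6.68 ± 0.67 and 4.44 ± 0.71. The glucose stationary replicates lay apart, with replicates 2 and 3 near an even floor: clpA stood at 18449.9 ± 22627 CPM in stationary and 851 ± 19.999 CPM in exponential phase. With Glc_Sta replicate 1 as the only stationary library, its spread taken from the other groups, the chitin list did not pass (median 1.88, adjusted p = 0.165). Without that replicate the median of the flagellum list moved to 0.52 and it did not pass (adjusted p = 0.161). In total 3005 genes differed (1583 higher and 1422 lower in stationary phase; edgeR), 2503 by at least 2-fold. Totals shifted the median by 0.908 and moved the share higher from 52.7% to 72.2%.

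On chitin few genes separated the phases. Of 53 ribosomal protein genes 31 fell in stationary phase and 22 did not pass (40 fell adjusted over the list alone; median -1.18, camera adjusted p = 1.06e-11, and adjusted p = 0.622 with an estimated correlation), with rpmC and rpsQ (CJA_0708) at -1.84 ± 0.37 and -1.75 ± 0.35, rplJ at -1.58 ± 0.40 and rpmG at -2.65 ± 0.31 (6.87 ± 1.24 against 43.3 ± 15.1 CPM). On chitin only the stationary libraries held the features counted in some groups only, so phase and that difference cannot be told apart. rpmG was also lower on GlcNAc than on glucose in exponential phase (-2.32 ± 0.28), where only the GlcNAc libraries held these features. The authors' table gave -0.02 there (DESeq2 adjusted p = 0.790). Of 14 ATP synthase and NADH dehydrogenase genes 4 fell and 10 did not pass (11 fell adjusted over the list alone; median -0.70, camera adjusted p = 0.00104, and adjusted p = 0.719 with an estimated correlation), with atpH at -1.29 ± 0.34. None of the 9 chitin degradation genes passed over all genes (4 fell adjusted over the list alone), nor did any of the 46 flagellum genes. CJA_3054 fell by 2.98 on the log2 scale, the cellulase gene cel5B changed by -1.26 ± 0.25 and the xylanase gene xyn10C (CJA_3066) by 1.03 ± 0.27, and CJA_2644, which was higher in all groups holding the features counted in some groups only, by 5.98 ± 0.35. In total 325 genes differed (188 higher and 137 lower in stationary phase; edgeR), 245 by at least 2-fold; 77 of the 325 were features counted in some groups only, and 777 passed an unadjusted p of 0.05. The count was 855 in a fit of the chitin libraries alone and 528 with DESeq2. It was 208 without Chitin_Exp replicate 1 and 214 without Chitin_Sta replicate 2. The calls of rplJ, atpH and xyn10C were lost without Chitin_Exp replicate 1 (adjusted p = 0.117, 0.151 and 0.139), Chitin_Sta replicate 1 (0.0939, 0.0909 and 0.0898) or Chitin_Sta replicate 2 (0.103, 0.115 and 0.105). Those of atpH and xyn10C were also lost without Chitin_Exp replicate 2 (0.0550 and 0.0604) and by totals (0.0756 and 0.429). That of xyn10C was lost as well with the features counted in some groups only left out (0.97, adjusted p = 0.068). With all 24 files as labelled all 3 were lost (0.0757, 0.223 and 0.502) and the count was 183. Totals shifted the median by -0.145; the share higher was 57.8%, or 36.7% without the features counted in some groups only.

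**Figure D3:**
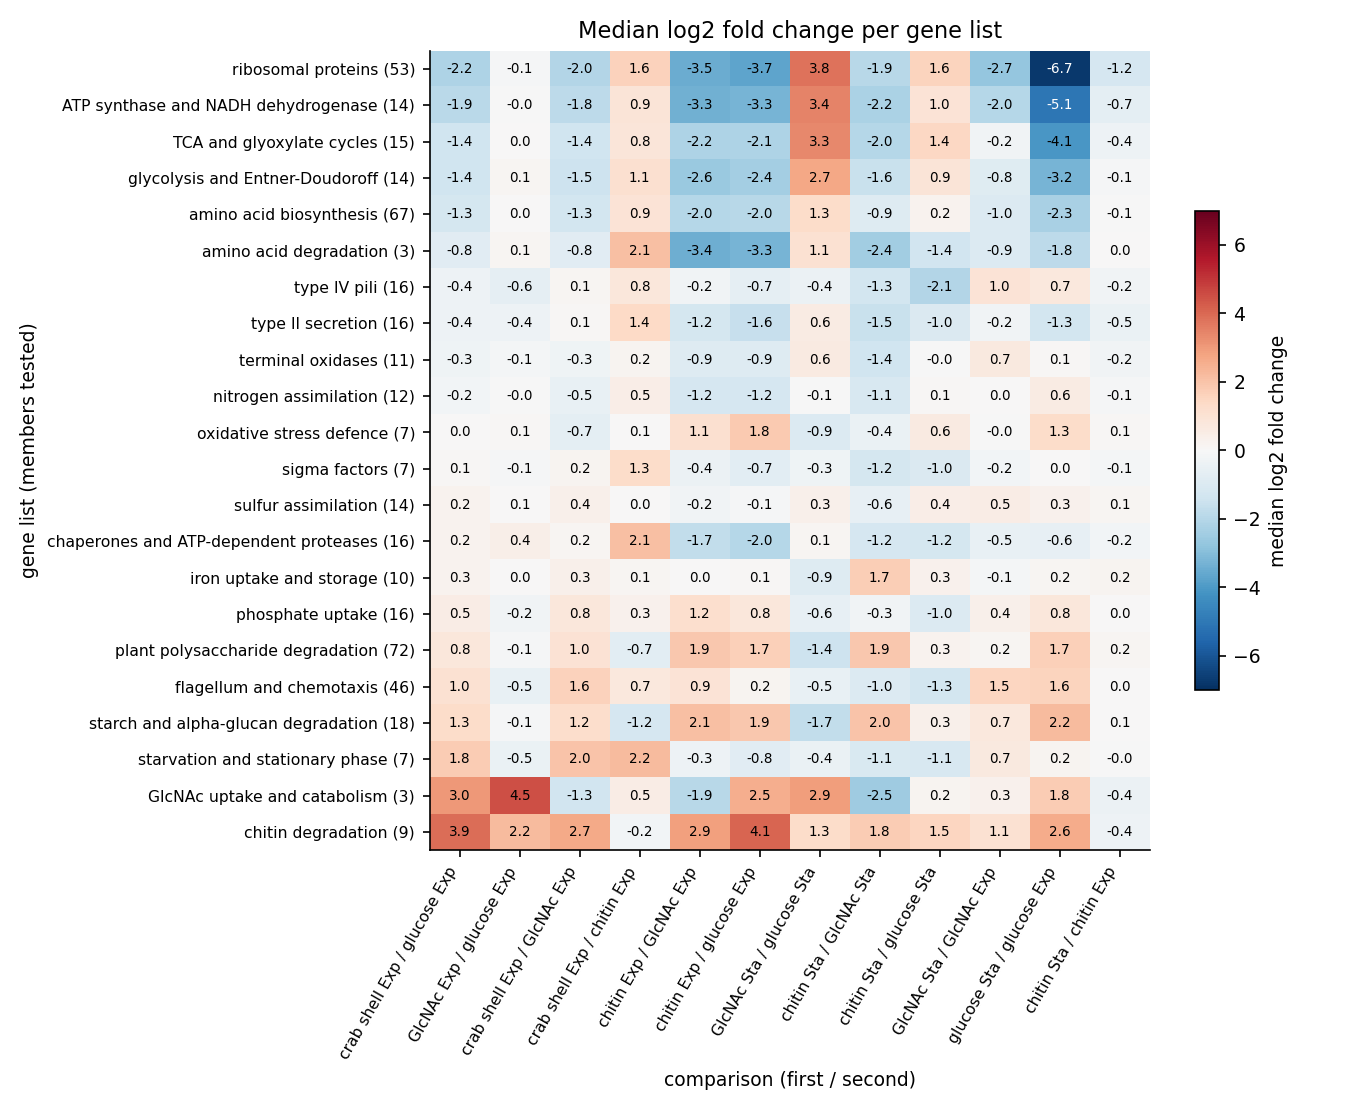
Median log2 fold change (colour and printed value, first group over second) of each gene list in the 12 comparisons made from counts; the number of genes tested is beside each list name. Ribosomal protein genes have medians of -2.19 on crab shell against glucose and -6.74 in glucose stationary phase. The median of the chitin list lies above 0 wherever crab shell or chitin is set against a single sugar. It also lies above 0 without a polymer, for GlcNAc against glucose in each phase and for stationary against exponential glucose.

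Crab shell in stationary phase is described from the authors' tables alone, since its count files were copies. In the authors' comparison of the crab shell phases (DESeq2), 762 genes differed, with 320 higher and 442 lower in exponential phase. Of 53 ribosomal protein genes 35 were higher in exponential phase and 18 did not pass (median 1.00), with rpsM at 1.39 ± 0.33, and of 46 flagellum and chemotaxis genes 18 were higher and 28 did not pass, with fliD at 1.40 ± 0.31. Of 9 chitin degradation genes only cbp33/10B passed, higher in exponential phase by 1.06 ± 0.39, and cbp33A was at -0.12 ± 0.39. Of 72 plant polysaccharide genes 24 were lower in exponential phase and 4 higher, with cel5H at -2.04 ± 0.41; cspD was at -1.56 ± 0.32 and hspC2 at -1.69 ± 0.39. CJA_3182 and CJA_0083 were lowest, at -3.01 ± 0.49 and -2.57 ± 0.48, and CJA_3518 was highest, at 2.02 ± 0.36. Against glucose in stationary phase 1534 genes differed (771 higher and 763 lower on crab shell), with 5 chitin genes higher and 4 not passing. These included cbp33A at 5.19 ± 0.53, chi18D at 3.36 ± 0.32 and chi18C at 2.37 ± 0.42. Ribosomal protein genes were higher in 50 of 53 cases (median 2.84), with rpsC at 4.17 ± 0.32, and chaperone genes in 9 of 16, with groL at 3.48 ± 0.50, while 25 of 46 flagellum genes and 10 of 16 type IV pilus genes were lower and CJA_0382 was at -5.99 ± 0.75. This comparison too includes glucose stationary replicates 2 and 3, whose low genes lay close to an even floor. Against chitin in stationary phase 2775 genes differed (1435 higher and 1340 lower on crab shell). Of 16 chaperone genes 14 were higher, with dnaK at 4.72 ± 0.39 and hspC2 at 4.49 ± 0.40. Of 18 starch genes 13 were lower and 3 higher, with amy13A at -4.11 ± 0.45. Of 72 plant polysaccharide genes 41 were lower and 18 higher. Of 9 chitin degradation genes 2 were higher, 3 lower and 4 did not pass, with cbp33A at -0.002 ± 0.46. None of these crab shell stationary values could be recomputed from counts, and the authors' table of crab shell against GlcNAc in stationary phase is not used here, because its GlcNAc mean correlated with the GlcNAc exponential counts at r = 0.972 across genes and with the stationary counts at 0.773.

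The response to GlcNAc against glucose differed between phases for 1834 genes (863 with a larger and 971 with a smaller log2 fold change in exponential than in stationary phase; edgeR test of the difference), 1570 of them by at least 2-fold. The GlcNAc genes rose in both phases but more in exponential phase. For nagK the difference was 3.42 ± 0.82, for nag9A 1.48 ± 0.57 and for nagB 1.39 ± 0.53. Among the chitin genes chi18B and chi18D had differences of 2.68 ± 0.67 and 2.02 ± 0.45, and that of cbp33A was -0.95 ± 0.38 (adjusted p = 0.0475). chi18A showed none that passed (-0.08 ± 0.49, adjusted p = 0.920). For ilvC the difference was -6.35 ± 0.44: it did not pass between GlcNAc and glucose in exponential phase (-0.14) and was higher on GlcNAc by 6.21 in stationary phase. All of these differences include the glucose stationary replicates, of which 2 and 3 lay near an even floor. With all 24 files as labelled 975 genes passed.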

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

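The 2 tests limited to genes with a mean of at least 10 counts, the 3 tests on the chitin phases and the test of swapped crab shell phases were chosen only after the result was seen; the others were written down before.

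Named genes were listed here when their response to GlcNAc against glucose differed between phases by at least 4 on the log2 scale, by edgeR's test of the difference. Values are the log2 fold change in exponential minus that in stationary phase. Positive differences were found for CJA_0382 (7.52), CJA_0381 (4.36), CJA_3057 (4.35) and the oxidase genes coxB (4.21) and coxG (4.02), and for CJA_0351 (4.24), a fitted value that rests on 2 counts on glucose in exponential phase. Negative differences were found for CJA_0065 (-7.71), CJA_3113 (-7.7), ilvC (-6.35), CJA_0058 (-5.21), ccoN (-4.81), sucC (-4.71), eno (-4.15) and atpE (-4.08). The ribosomal protein genes rpmC (-4.89), rpsC (-4.54), rplL (-4.34), rpsQ (-4.3) and rplJ (-4.15) differed the same way, and so did rpsM (-4.09) and CJA_2062 (-6.43), which the rule for naming genes did not bring into this comparison. All of these differences involve glucose stationary libraries 2 and 3, which are weighed next.

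The 3 glucose stationary libraries differed widely among themselves, libraries 1 and 3 correlating at r = 0.715 over the log2 counts of the 3502 genes of known length used in these tests. Adding an even floor of counts per kilobase to library 1 gave a lowest correlation of 0.766 with libraries 2 and 3. This was below the bound of 0.8 set beforehand and argues against such a floor as the whole cause. The floor moved library 3 from 0.721 to 0.766 and library 2 from 0.905 to 0.858. A test over genes with a mean of at least 10 counts, which left out 33 genes, was chosen after that result. There the floor moved library 3 from 0.686 to 0.891 and library 2 from 0.904 to 0.928. By the bounds set this decides nothing, and without those 33 genes the first verdict did not hold. Mixing in counts of a chitin library gave 0.816 over all genes and 0.756 over the better counted genes, and the latter argues against it. Leaving out 84 of the highest genes gave 0.684, which argues against a few genes taking most of the counts. A floor together with another difference stays open, and no biological explanation was tested.

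Few genes separated the chitin phases. The lowest ratio of lower quartile to 5th percentile among the chitin libraries was 2.288. This argues against an even floor as marked as in glucose stationary libraries 2 and 3. It cannot exclude a smaller floor. The 5th percentile was 0.155 to 0.185 of the mean in the chitin libraries, against 0.024 to 0.06 in the crab shell, GlcNAc and exponential glucose libraries. Fitting the 6 chitin libraries alone gave 855 genes in place of 325, against 3052 in a fit of the 5 GlcNAc libraries alone, which argues against a spread widened by the other groups as the whole cause. In 6 of 6 libraries the nearest library was of the same phase, which argues against swapped libraries. A physiological similarity of the phases, as in slow growth on chitin, stays open and was not tested.

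Crab shell exponential libraries resembled GlcNAc stationary libraries more than GlcNAc exponential ones. The crab shell stationary means recovered from 3 authors' tables also correlated better with GlcNAc stationary than with GlcNAc exponential means, by 0.12 to 0.133. This argues against swapped crab shell phases as the source of the resemblance. It cannot tell whether the phases were swapped. In the authors' table of the crab shell phases the exponential mean leaned alike, at r = 0.84 with GlcNAc stationary and 0.712 with GlcNAc exponential means. Without 111 of the highest genes the difference in correlation was 0.153, against 0.139 with them, which argues against a few genes taking most of the counts. Slower growth on crab shell is consistent with the median of ribosomal protein genes, -2.036 against GlcNAc in exponential phase and -2.721 between the GlcNAc phases. This is a hypothesis, and growth rates are not used here. In the authors' table of the crab shell phases 35 of 53 ribosomal protein genes were higher and 0 lower in exponential phase, the direction the labels give. An exchange of the GlcNAc labels was not tested.

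Other splits of the same 6 libraries into 3 and 3 were counted for each comparison of groups of 3. Each has 10 splits, so the share of splits cannot go below 0.1, and in each 1 split, the real one, gave as many genes. The real count and the highest other were 2566 and 0 for crab shell against glucose, 367 and 0 for GlcNAc against glucose, 2698 and 0 for crab shell against GlcNAc, and 2655 and 0 for crab shell against chitin. They were 2973 and 0 for chitin against GlcNAc and 2899 and 0 for chitin against glucose in exponential phase, and 2656 and 731 for chitin against glucose in stationary phase. Between phases they were 3005 and 223 on glucose and 325 and 15 on chitin. These used edgeR.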

How the results depend on the processing

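Tests with all 24 files as labelled, without the shared stationary file, without features counted in some groups only, and with glucose stationary replicate 1 alone were chosen only after the result was seen. Where values changed, the cause was not tested.

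Of the counts of changed genes, 5 comparisons and the interaction moved by more than 1.5 times under some setting. DESeq2 gave 528 genes between the chitin phases, against 325. Fitting only the compared groups gave 1911 genes for GlcNAc against glucose in exponential phase, 1009 in stationary phase, 1576 for chitin against glucose in stationary phase and 855 between the chitin phases. All 24 files as labelled gave 1573 genes for chitin against GlcNAc in stationary phase, 183 between the chitin phases and 975 for the interaction. Leaving out 1 library at a time gave 208 to 352 genes between the chitin phases. Leaving out a GlcNAc stationary library leaves 1, assumed to vary like the other groups.

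For single genes, 6 values changed direction. On GlcNAc against glucose in stationary phase hex20A was 0.54 (adjusted p = 0.379) and chi18B 1.03 (adjusted p = 0.161) with all 24 files as labelled, and chi18B was 1.61 with glucose stationary replicate 1 alone (adjusted p = 1.74e-04) and ranged from -0.94 (adjusted p = 0.00358, without replicate 1) to 0.0722 when single libraries were left out. The others were cbp33A and chi18A: cbp33A between crab shell and chitin was -0.43 by library totals (adjusted p = 0.351), and chi18A between crab shell and GlcNAc ranged from -0.37 to 0.62 when single libraries were left out. Apart from leaving out libraries, 2349 gene values kept their direction and side of the threshold, 41 lost and 5 gained a call; when libraries were left out, 1340 kept them, 26 lost and 3 gained. Of 240 list tests 85 passed with the preset correlation, 4 with an estimated correlation and 154 with fry.

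With the replicate number as a block (replicate block), 346 genes differed between GlcNAc and glucose in exponential phase and 293 between the chitin phases. The main fit was planned without this block. Libraries of the same number did not resemble each other on average (mean r = -0.026 after removing group means, single pairs from -0.626 to 0.448). Pairs of different number ranged from -0.54 to 0.623. Scaling mattered most between chitin and the other substrates in exponential phase, where totals moved the median of all genes by up to 1.55.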

Other observations

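All observations here were chosen only after the result was seen, and no further tests were run for them. CJA_0065, CJA_3113 and CJA_2062 were high in both GlcNAc stationary libraries and in no other library: CJA_0065 stood at 3042 and 2500.0 CPM there and at most 15.02 CPM elsewhere, and CJA_3113 at 3030 and 3057 CPM and at most 29.5 CPM elsewhere. CJA_2062 stood at 1805 and 1659 CPM there and at most 75.9 CPM elsewhere. The files give no names for these genes.

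The authors' table named for GlcNAc exponential against GlcNAc stationary runs opposite to its name: its log2 fold changes correlated at r = -0.932 across genes with those from the counts taken in the order of its name. Whether its groups were divided in the other order or its inputs were exchanged was not tested.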
